A study of Mus musculus with 8 samples.

How the data were processed

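Each of the 8 samples was a pair of whole kidneys of a C57BL/6 mouse embryo at embryonic day 16.5, per the labels, 4 wildtype (WT) and 4 with a conditional knockout of Dot1, taken here as Dot1l, in the lineage of Six2-positive nephron progenitors (KO). The series' design text names them biological replicates. Groups and replicate numbers were taken from the labels. Per the labels' protocols, total RNA was purified on RNeasy columns, amplified linearly and labelled with Cy3 or Cy5. The labels put the sample in Cy5 and the same WT1 RNA in Cy3 on every array, with no dye swap, so a dye effect that is equal on all arrays cancels in the difference of the groups, and the WT1 array measured WT1 RNA against itself.

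The deposited scanner output was made with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Per the file headers, the intensity columns used were the median red and green spot signals and their local background medians, on a linear scale and without normalization. The deposited processed intensity columns were background-subtracted and dye-normalized by the software, and the deposited log ratio is the log10 of processed red over processed green. Per the file headers, other columns hold flags of 0 or 1 for spots that are well above background, saturated or not uniform. The deposited values of the whole series held these log10 ratios, within 0.497% of each array's own, and the median of each column was 0; its scale, centring and direction were thus known. All 8 arrays lay on 1 slide with 1 scan date. Each of the 2 slide rows held a single group, and the 4 slide columns matched the replicate numbers.

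In R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, the median signals were background-corrected with normexp (offset 50) and normalized by loess within each array, with control spots at weight 0 and left out afterwards, and with no step between arrays. Spot readings that the software marked as outliers were left out (1765, or 0.372%), and no spot was saturated. Spots of the same probe were averaged. A probe was kept if it was well above background in the red channel on at least 4 of the 8 arrays. Of 55681 distinct probes, 27509 were given a symbol by matching the accession, without version, to the RefSeq gene names of assembly GRCm38.p6, which was used for names and gene order only because the file headers name another build. These were 27509 of the 29150 probes with a RefSeq accession, no probe matched several genes, and 20887 genes were named. Of the 18153 kept probes with a symbol, the probe with the highest mean intensity stood for its gene, a rule that mattered for 3524 genes with several kept probes. Only probes with a symbol entered the main test, a choice made after the data were seen.

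Differences between KO and WT were tested for 13974 genes with limma's lmFit and eBayes on the log2 ratios, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the moderated standard error of the difference, with 4 arrays per group. The number of arrays limits the precision. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over 22 lists, and again with an estimated correlation, with which no list passed. Where a list passed at the preset value, its estimated correlation was higher, between 0.0546 (stroma) and 0.659 (proximal tubule). Every list that passed thus rests on the preset value. The lists covered nephron progenitors, committing nephrons, podocytes, proximal tubule, loop of Henle and distal tubule, ureteric bud tip, collecting duct, stroma, renin cells, endothelium, macrophages and other leukocytes, erythroid cells, adrenal and sympathetic tissue, cell cycle, p53 targets, the DOT1L and elongation complexes, Hox and Meis genes, Wnt targets, ion transport, immediate early genes, hypoxia, and fibrosis and injury. A further list of sex-linked genes served as a sample check. Dot1l, Six2 and Six3 were also tested with a two-sided exact permutation test over 70 labelled splits, for which the smallest possible p is 0.029. A gene below background on all arrays of a group was given a bound, from the lowest signal among probes well above background after loess and Aquantile, which is open to dye bias without dye swaps.

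The main design, the gene lists, the rule for named genes and the alternatives listed first below were fixed before the data were examined. The rule named Dot1l, Six2 and Six3; the 8 genes with the largest rise and the 8 with the largest fall among those that passed without overlap of the groups; for each list, up to 4 members with the smallest p among those that passed, or up to 2 as values where none did; and the sex-linked genes. Members named beyond these were chosen after their values were seen, and a gene that the rule named is not reported here. The design had named mean spot signals; the median signals were used because these are what the scanner output holds. Same-numbered samples deviated from their group means together, with correlations across genes of 0.138, 0.373, 0.257 and 0.304, all above 0.1, so the numbers, which are also slide columns, were treated as pairing the samples. WT4 correlated more with KO1 (0.369) than with KO4, and WT1 reached 0.0937 with a KO sample of another number. A fit with the number as a block was run.

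The alternatives chosen at the outset were no background correction, the software's own ratios, the deposited series values, median centring, Aquantile or scale normalization between arrays, the red channel alone, no filter or a stricter filter on dim probes, other rules for several probes, trend and robust eBayes, array weights, the replicate block, an estimated correlation in camera, and leaving out each array in turn. Chosen after the data were seen were leaving out the WT1 and KO1 arrays, alone and together with 5 of these settings, sex as a model term, and a test that included identifiers without a symbol. The analysis was tested on simulated data for the KO and WT comparison, with 13974 genes of which 200 changed. It recovered 61.2% of 67 genes changed by 0.5 on the log2 scale, 97% of 67 changed by 1 and all 66 changed by 2. The simulated noise was independent for each gene and array, and the changes were added to log ratios after normalization. Correlation between genes, the pairing by number and the normalization were thus not part of this test. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6. Genome coordinates and the position of the Dot1l probe relative to the deleted part were not analysed here.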

Results

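Gene expression was measured in whole mouse kidneys at embryonic day 16.5, the stage at which nephrons are still forming from a pool of progenitor cells under the kidney capsule. The kidneys came from 4 wildtype (WT) C57BL/6 embryos and from 4 embryos in which Dot1l, the histone H3 lysine 79 methyltransferase, was deleted in cells that express Six2, the transcription factor that marks this progenitor pool (KO). Each sample was labelled with Cy5 (red) and hybridised together with Cy3-labelled (green) RNA of the WT1 kidneys. Every value is thus a log2 ratio of a sample over that common reference. The WT1 array held WT1 RNA in both colours. After filtering, 13974 named genes were tested. The number of arrays limits the precision. The red negative-control spots had medians of 58 to 61 scanner units on 6 arrays, but 1361 on the WT1 array and 478.2 on the KO1 array. The green signal of the same reference RNA correlated across probes with that of the 6 other arrays at a median r of 0.505 for WT1 and 0.822 for KO1, against 0.970 to 0.974 for these 6.

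**Figure D1:**
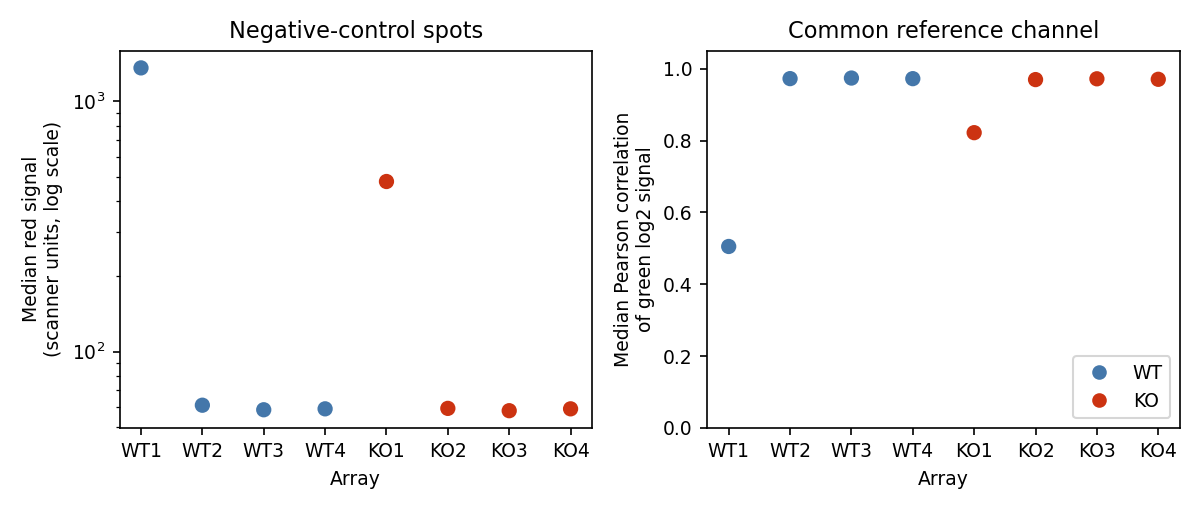
The left panel shows the median red signal of the negative-control spots on each of the 8 arrays, on a log scale, and the right panel the median Pearson correlation across probes of each array's green log2 signal with those of the other WT2 to WT4 and KO2 to KO4 arrays. WT arrays are blue and KO arrays red; WT1 (1361 units, r = 0.505) and KO1 (478.2 units, r = 0.822) stand apart from the 6 others.

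The sexes of the embryos were not balanced between the groups. Ddx3y, a Y-linked gene, had log2 ratios of 2.31, 2.90, 3.19 and 3.15 on the 4 KO arrays and of 3.30 on the WT2 array, and of -0.11, 0.08 and -0.11 on the WT1, WT3 and WT4 arrays. Xist, which is expressed from the inactive X chromosome, was low on the same 5 arrays, from -2.68 in WT2 to -1.79 in KO1, and lay between -0.40 and -0.02 on the other 3. All 4 KO embryos were thus male by these markers, and among the WT embryos 1 was male and 3 were female. Group also coincided with the row of the slide, since all WT arrays lay in row 1 and all KO arrays in row 2, so row and group could not be told apart.

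The targeted gene was examined in every sample. The Dot1l probe gave log2 ratios of -0.23, -0.21, -0.09 and -0.09 in WT1 to WT4 and of -0.13, -0.04, -0.21 and -0.11 in KO1 to KO4, a difference of 0.03 ± 0.08 (SE, n = 4 per group; limma adjusted p = 0.924; two-sided exact permutation p = 0.657 over 70 splits). The whole kidney contains many cells outside the Six2 lineage, and where this probe lies relative to the deleted part of the gene was not analysed here. The probe therefore does not check the labels. Six2 itself differed by -0.21 ± 0.12 (adjusted p = 0.439), and its second probe gave -0.20. Six3, a related homeobox gene next to Six2 on the chromosome, was higher in KO by 1.09 ± 0.16 (adjusted p = 0.00508; 4 of 4 KO arrays above every WT array). Red Six3 signal was 273 to 684 units on KO2 to KO4 and 59.5 to 62 units on WT2 to WT4, where the probe was not well above background. The green Six3 signal, which comes from the same reference RNA on every array, was 51 to 83 units on KO2 to KO4 and 21 to 24 units on WT2 to WT4, where the green negative-control medians of these 6 arrays were 21 to 26 units. No exact size of the Six3 change is therefore given by this probe.

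The question of the main comparison was which genes differ in kidneys whose nephron progenitors lack Dot1l. Cited1, a transcriptional coregulator of the earliest nephron progenitors, had the largest decrease: it fell by 2.72 ± 0.10 on the log2 scale (SE; 6.60-fold lower, adjusted p = 2.85e-08), the homeobox gene Meox2 by 1.93 ± 0.20 (adjusted p = 0.000973) and the signalling adaptor Traf1 by 1.52 ± 0.09 (adjusted p = 4.15e-06). Among the other genes with the largest decreases were Hes5, a Notch target (-1.42), Phf19, a Polycomb-associated factor (-1.13), Kazald1 (-1.11), the homeobox gene Uncx (-1.11) and R3hdml (-1.09). The largest increases were those of Cyp2e1, a cytochrome P450 of proximal tubule and liver, which rose by 2.24 ± 0.26 (4.71-fold, adjusted p = 0.00157; 1.23 at its second probe), of the kallikreins Klk1b5 (1.88), Klk1b3 (1.63), Klk1 (1.61) and Klk1b4 (1.38), and of Guca2b, which encodes uroguanylin (1.44). Nat8, an acetyltransferase gene of tubular cells (1.41), and Ugt2b38, a UDP-glucuronosyltransferase gene (1.28), rose as well. The kallikrein and Ugt2b genes are families of near-identical sequences, so their probes may share transcripts and the member concerned is uncertain. These 16 genes had the largest changes among those that passed without overlap of the groups. That the 4 KO arrays lay beyond the 4 WT arrays for each was thus a condition of the choice.

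Across the 13974 genes, 295 passed an adjusted p of 0.05 in limma, 219 of them higher and 76 lower in KO. Of these, 16 were higher and 10 lower by at least 2-fold, and in 291 the groups did not overlap, an arrangement that chance gives in 2.86% of genes and that 9.26% of all genes showed. Ripply2, named here after its values were seen, was the only called gene below background in every array of a group, and was at least 1.81-fold lower in KO. With the replicate number as a block the count was 554 (443 higher, 111 lower). The count was 124 (74 higher, 50 lower) from the scanner software's own ratios, and 0 with median centring in place of loess or with the red channel alone. In these settings limma gave 177 and 107 genes at an unadjusted p under 0.05. Chance gives 698.7, and the main comparison gave 2029. It was 83 without KO4, 122 without WT4, 143 without KO2, 148 without WT2 and 188 without WT1. Without WT1 and KO1 together it was 244 (175 higher, 69 lower), and 181 of the 295 genes passed again. Sex as a model term sets the KO arrays against the WT2 array alone, so its differences carry that array's own deviation. With it Cited1 differed by -2.77, Meox2 by -2.04, Traf1 by -1.60, Kazald1 by -1.32, Uncx by -1.28 and R3hdml by -1.04. Lhx1 differed by -1.32, with WT2 at 0.78 and the other WT arrays at 0.12 to 0.23. Against WT2 all 295 genes kept their direction. For the 291 without overlap of the groups this was fixed in advance, since WT2 was among the WT arrays of the call. The median size of the change of the 295 genes was 0.599, against 0.57 in the main comparison, while the median SE rose from 0.105 to 0.163. WT2 had entered the choice of these genes, so neither value tests the effect of sex on them. With the red channel alone the differences of Phf19, Bmp2 and Egr1 turned to 0.30, 0.11 and 0.22. Without WT1 and KO1, none of 61 named genes, Dot1l apart, changed direction in the red channel alone.

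Of the list of nephron progenitor genes, 27 were measured, of which 10 fell and none rose over all genes tested, and 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.60e-17; adjusted p = 0.108 with an estimated correlation). Beside Cited1, Meox2, Traf1 and Uncx, the genes that fell were Capn6 (-0.98), Spock2 (-0.78), Tmem100 (-0.55), the zinc finger gene Wt1 (-0.40), the integrin subunit gene Itga8 (-0.40) and Hoxd11 (-0.37, against -0.18 at a second probe). Of the members that did not pass over all genes, Hoxc10 (-0.44), Eya4 (-0.39) and Meox1 (-0.37) were lower and Fgf20 (0.40) was higher. Smaller differences were those of Eya1, a cofactor of Six2 (0.21 ± 0.16, SE), Gdnf, the growth factor that draws in the ureteric bud (0.08 ± 0.11), and Osr1 (-0.06 ± 0.12). The list median was -0.23. Against the single male WT array the list median was -0.26, and Cited1 was lower by 2.77. Without WT1 and KO1, 9 members fell.

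Of 25 measured genes that mark cells committing to nephron formation, 6 fell in the whole kidney and none rose over all genes tested, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.73e-06; adjusted p = 0.186 with an estimated correlation). They were Hes5 and 2 further components of Notch signalling, the ligand gene Dll1 (-0.60 ± 0.09, SE) and the glycosyltransferase gene Lfng (-0.47), together with Fgf8 (-0.73 ± 0.09), Bmp2 (-0.65 ± 0.10) and Lhx1 (-0.86), the last a transcription factor of the renal vesicle. The inducer Wnt4 differed by -0.06 and Pax8 by 0.00. The other Fgf8 probes gave -0.48 and, where dim, -0.04. Against the male WT array, WT2, Hes5 differed by -1.65, Fgf8 by -0.67, Bmp2 by -0.76 and Lhx1 by -1.32. For Lhx1 WT2 itself was high, at 0.78 against 0.12 to 0.23 in the other WT arrays. The list median was -0.15 against WT2, -0.08 in the main comparison and -0.04 without WT2.

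**Figure D2:**
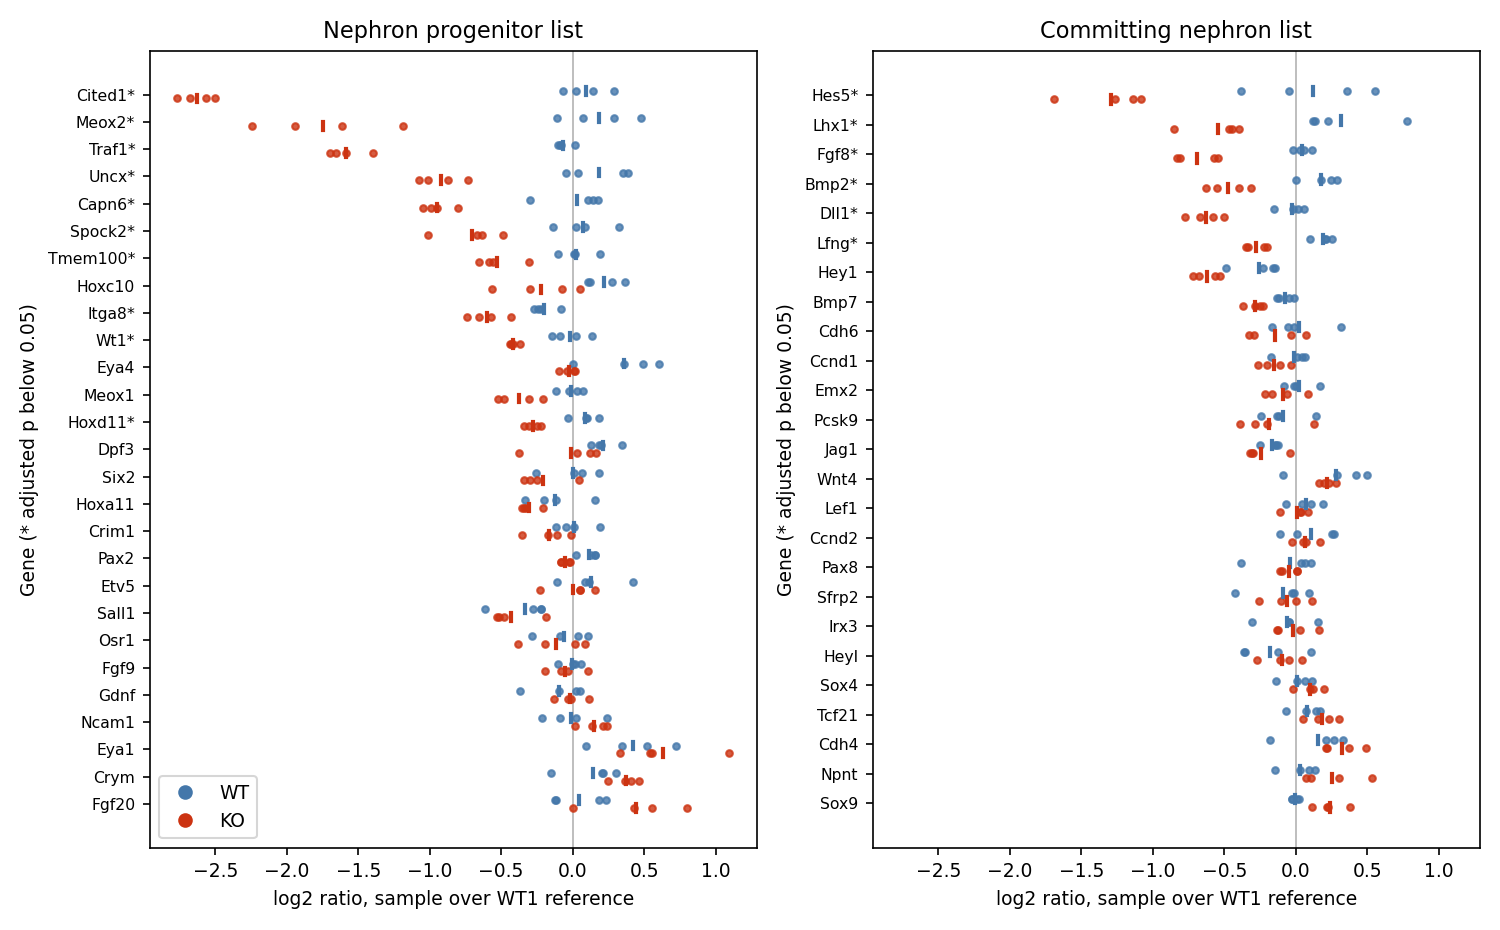
Each dot is the log2 ratio of a gene on an array, WT in blue and KO in red, and each vertical tick is a group mean (n = 4 arrays), for the measured members of the nephron progenitor list (27 genes, left) and the committing nephron list (25 genes, right); asterisks mark an adjusted p below 0.05. Cited1, Meox2 and Traf1 lie far below WT on every KO array, while Six2, Eya1, Gdnf, Wnt4 and Pax8 overlap between the groups.

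Of 37 measured proximal tubule genes, none passed over all genes tested and 7 rose adjusted over the list alone, with a median of 0.36 (camera adjusted p = 2.34e-07; adjusted p = 0.563 with an estimated correlation). Dab2, an endocytic adaptor, differed by 0.43 ± 0.11 (adjusted p = 0.0564) and Slc27a2, a fatty acid transporter, by 0.77 ± 0.19 (adjusted p = 0.0664). In this list WT4 was the lowest WT array in 34 genes and KO3 the highest KO array in 33, the median was 0.23 without WT4, and the groups did not overlap in 6 genes. With the replicate block, 6 proximal tubule genes rose over all genes tested, among them Dab2 (adjusted p = 0.0209) and Slc27a2 (adjusted p = 0.0142). Of 22 further ion and fluid transport genes, 6 rose and 1 fell, or 13 and 1 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 8.51e-08; adjusted p = 0.38 with an estimated correlation). Fxyd4, a regulator of the sodium pump (0.79 ± 0.16), the chloride-bicarbonate exchanger gene Slc26a4 (0.76 ± 0.17), the potassium channel gene Kcnj16 (0.67 ± 0.13) and Slc22a18 (0.60 ± 0.13) rose, and Kcnj10 fell by 0.55. Without WT1 and KO1, 3 of these transport genes rose and none fell, and with the replicate block 10 rose and 1 fell. In the transport list too, WT4 was the lowest WT array in 19 genes and KO3 the highest KO array in 18. The median of this list was 0.39 without WT4 and 0.39 without KO3. In 23 genes of the loop of Henle and distal tubule, 1 fell, the transcription factor gene Sim2 (-0.73 ± 0.14, against -0.09 at a second, dimmer probe), and 3 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.507 with an estimated correlation). The shift of this list did not pass without WT1 (adjusted p = 0.0564) or with sex as a term (adjusted p = 0.738). It did not pass without WT1 and KO1 with the replicate block (adjusted p = 0.0677), the software's ratios (adjusted p = 0.0813) or the red channel alone (adjusted p = 0.123). With the replicate block 1 of its members rose and 5 fell.

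Of 27 stromal genes, 6 rose and none fell over all genes tested, and 12 rose adjusted over the list alone, with a median of 0.31 (camera adjusted p = 4.36e-08; adjusted p = 0.108 with an estimated correlation). They included Pdgfra, a receptor of fibroblasts (0.73 ± 0.11, SE), the matrix proteoglycan genes Lum (0.70 ± 0.13) and Dcn (0.53 ± 0.09), and Penk, a marker of medullary stroma (0.55 ± 0.10). Without WT1 and KO1, 3 stromal genes rose and the list median was 0.25 (camera adjusted p = 2.22e-07), and with the replicate block 9 rose. Of 19 macrophage and leukocyte genes, 5 rose, and 13 rose adjusted over the list alone, with a median of 0.35 (camera adjusted p = 1.22e-10; adjusted p = 0.108 with an estimated correlation). Examples were the mannose receptor gene Mrc1 (0.56 ± 0.08), Pf4 (0.54 ± 0.10), the chemokine receptor gene Cx3cr1 (0.51 ± 0.09) and F13a1 (0.47 ± 0.09, against 0.01 at a second, dim probe), and 3 rose without WT1 and KO1, where the list median was 0.37. With the replicate block 7 rose. In the macrophage and leukocyte list WT4 was the lowest WT array in 14 genes, and the median was 0.25 without WT4. In the list of interstitial fibrosis and injury, 1 of 16 genes rose, Krt20 (0.70 ± 0.13), an epithelial keratin, and 3 rose adjusted over the list alone (camera adjusted p = 0.00553; adjusted p = 0.211 with an estimated correlation, and 0.212 with sex as a term). With the replicate block 3 rose over all genes tested. Against the male WT array alone the medians of the stromal and macrophage lists were 0.21 and 0.30.

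**Figure D3:**
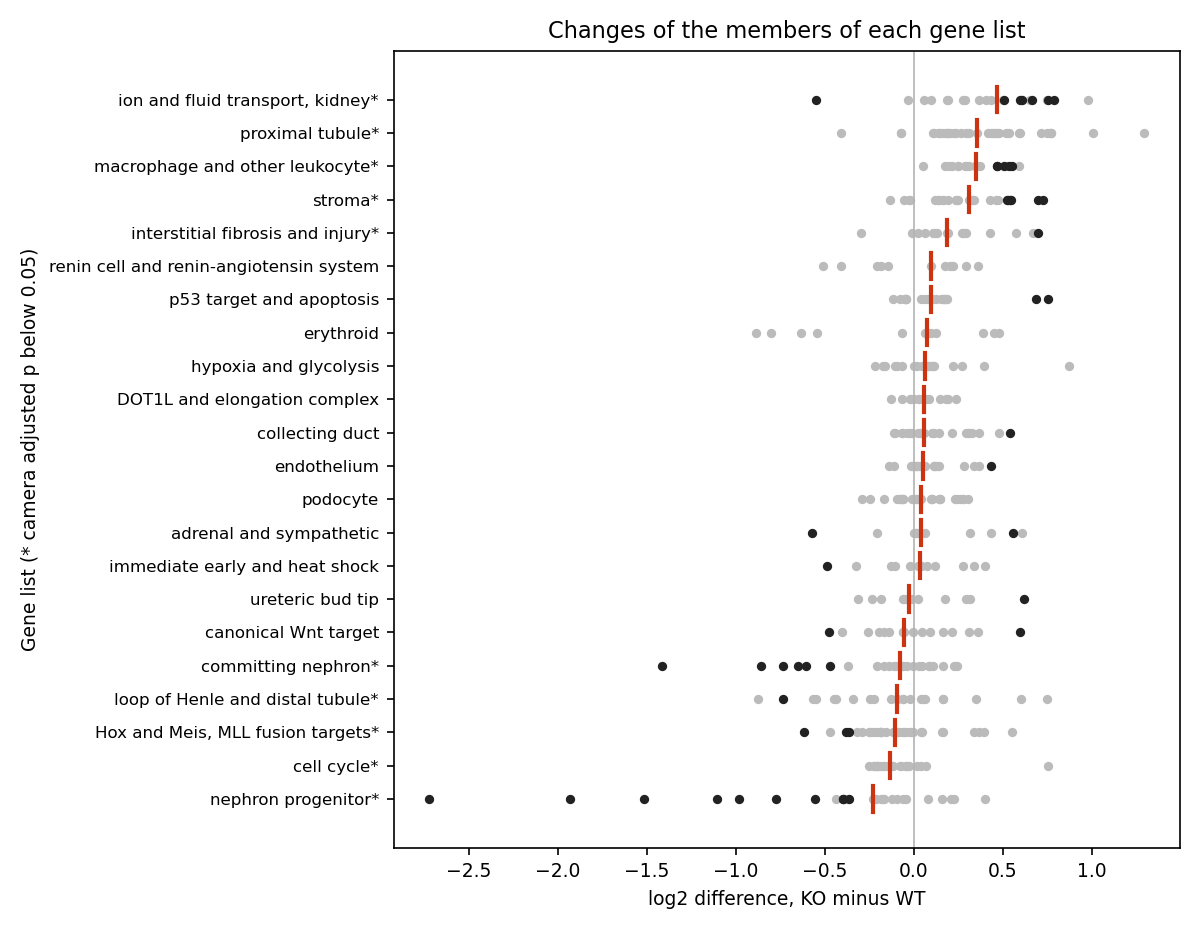
Each dot is the log2 difference, KO minus WT (n = 4 arrays each), of a measured member of the gene list named on the left, black where its adjusted p was below 0.05 and grey otherwise, and each red tick is the list median. Asterisks mark the 10 lists with a camera adjusted p below 0.05 at the preset correlation, from the nephron progenitor list (median -0.23) to ion and fluid transport (median 0.47). None passed with an estimated correlation.

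Genes tied to DOT1L function in other settings were examined next. Of 32 Hox, Meis and other targets of MLL fusion proteins, which act through DOT1L in leukaemia, 3 fell and none rose over all genes tested, and 6 fell and 2 rose adjusted over the list alone (camera adjusted p = 9.56e-06; adjusted p = 0.187 with an estimated correlation). The 3 were the posterior genes Hoxa9 (-0.62 ± 0.10, SE), Hoxd10 (-0.38 ± 0.09) and Hoxd11, which the progenitor list also holds. Second probes, with overlapping groups, gave -0.41 for Hoxa9 and -0.18 for Hoxd11. With the replicate block 1 gene of this list rose and 4 fell. No gene of the DOT1L and elongation complex list passed (15 measured, none adjusted over the list alone either; camera adjusted p = 0.768). Its lowest p values were those of Eaf2 (0.24 ± 0.11, adjusted p = 0.35) and Aff1 (0.18 ± 0.10, adjusted p = 0.467), which were 0.14 and 0.10 without KO3. The cell cycle list had a median of -0.13 over 26 genes with none passing in either way of adjustment (camera adjusted p = 0.000104; adjusted p = 0.563 with an estimated correlation). The list median was -0.06 without WT4 and -0.06 without KO3. Mcm3 differed by 0.76 ± 0.24 (adjusted p = 0.152), with WT3 alone at -1.40. It differed by 0.46 without WT3, and with the replicate block it passed (adjusted p = 0.0497). Mcm7 differed by -0.25 ± 0.09 (adjusted p = 0.195). The p53 target and apoptosis list did not pass as a set (21 genes, camera adjusted p = 0.148), though without the filter on dim probes it did (adjusted p = 0.0359). The list median was 0.10, and 0.16 against the male WT array. Its members Cdkn1a, the cell cycle inhibitor p21 (0.76 ± 0.13, adjusted p = 0.0107; -0.04 at a second, dim probe), and Perp (0.69 ± 0.10, adjusted p = 0.00645) rose, the same 2 genes that passed adjusted over the list alone.

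The remaining lists did not pass as sets in the main test, at the preset correlation. Of 25 podocyte genes none passed in either way of adjustment (camera adjusted p = 0.768), and Robo2 (-0.29 ± 0.08, adjusted p = 0.105) and Col4a3 (0.28 ± 0.08, adjusted p = 0.119) had the lowest p values. In the ureteric bud tip list, 1 of 12 genes rose, the retinoic acid synthesis gene Aldh1a3 (0.62 ± 0.10), and 2 adjusted over the list alone (camera adjusted p = 0.981). In the collecting duct list, 1 of 23 rose in both ways, Krt19 (0.54 ± 0.12), and the camera adjusted p was 0.148 in the main test. This set passed in camera without WT1 and KO1 (adjusted p = 0.004), without WT1 alone (0.0467) and without KO1 alone (0.0153). It also passed without the filter on dim probes (adjusted p = 0.0472) and with every kept probe tested (0.0243). Of 20 endothelial genes 1 rose, Sox17 (0.43 ± 0.10), and 2 adjusted over the list alone (camera adjusted p = 0.454). Among 17 canonical Wnt targets Sp5 rose (0.60 ± 0.11) and Myc fell by 0.48 ± 0.10, with 2 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.372). Among 10 adrenal and sympathetic genes, markers of tissue next to the kidney, Phox2a rose (0.56 ± 0.12) and Pnmt fell by 0.57 ± 0.11, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.662). Egr1 fell by 0.49 ± 0.11 as the single change among 14 immediate early and heat shock genes, with 1 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.662). None of 20 hypoxia and glycolysis genes passed over all genes, 1 was higher adjusted over the list alone, and Ndrg1 (0.87 ± 0.22, adjusted p = 0.0679) and P4ha2 (0.40 ± 0.15, adjusted p = 0.242) had the lowest p values. P4ha2 differed by 0.21 without WT4. Ndrg1 passed with the replicate block (adjusted p = 0.0209) and also without KO1. None of 11 renin cell and renin-angiotensin genes passed, 1 was higher and 1 lower adjusted over the list alone, and Akr1b7 differed by -0.51 ± 0.13 (adjusted p = 0.0616). None of 12 erythroid genes passed in either way; Alas2 differed by 0.48 ± 0.15 (adjusted p = 0.144) and Hbb-bh1 by -0.54 ± 0.18 (adjusted p = 0.171), or by -0.36 without WT4. With the replicate block 3 erythroid genes rose, among them Alas2 (adjusted p = 0.0268), and 3 adrenal and sympathetic genes and 2 endothelial genes rose. The camera adjusted p was 0.768 for each of the hypoxia, renin and erythroid lists. With the red channel alone the shifts of the committing nephron, macrophage, cell cycle, Hox and fibrosis lists did not pass. Without WT1 and KO1 these lists passed in the red channel alone, with camera adjusted p from 3.14e-12 (macrophage) to 0.00185 (fibrosis). The median, mean and set test pointed in different directions for the ureteric bud tip (-0.03, 0.04, up), renin (0.10, -0.01, down), erythroid (0.07, -0.10, down) and immediate early (0.04, 0.02, down) lists.

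**Figure D4:**
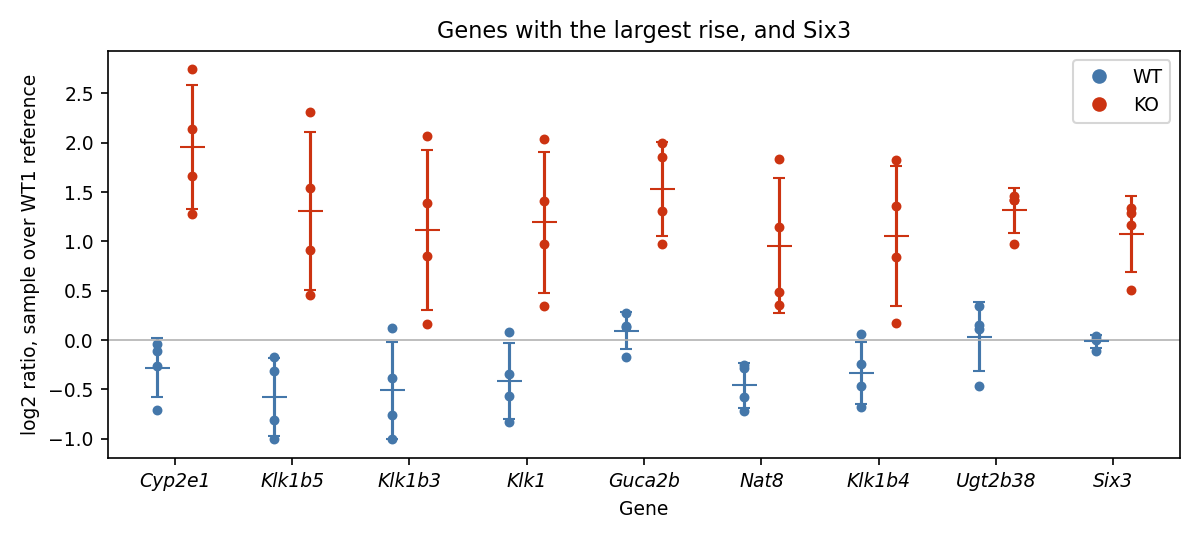
Dots are the log2 ratios of the 8 genes with the largest rise and of Six3 on each array, WT in blue and KO in red, and bars are the mean and SD of each group (n = 4). Every KO value lies above every WT value of the same gene, which was a condition for choosing the 8 genes. Cyp2e1 is highest (mean difference 2.24), and the lowest KO value of each kallikrein gene is that of KO1.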

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

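Of the tests in this part, only the count over other splits of the arrays and the comparison of progenitor markers were chosen before their results were seen; the tests on sex, the WT1 and KO1 arrays and Six3 were chosen only afterwards.

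Of 35 splits of the 8 arrays into 4 and 4, only the real one gave as many as 295 changed genes. The highest other count was 5. Most of these splits ignore the pairing by replicate number. Only 8 splits part every same-numbered pair, too few for a share under 0.05. The highest other count among those 8 was 0, but a test with so few splits cannot exclude chance. Without WT1 and KO1, 181 of the 295 genes passed again in the same direction, which argues against the nonspecific signal as the whole cause. Over 148 genes called between the female WT and the KO arrays, the male WT array lay at a median of 0.0204 of the way from female WT to KO, with an upper quartile of 0.267. With only 1 male WT array, whose own deviation enters these values, sex cannot be told apart from the knockout for the 295 genes as a set. Slide row stays confounded with group, and the loss of Dot1l, the difference the design names, stays open.

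Progenitor genes fell unequally. If the fall of Cited1 came only from an equal loss of all progenitor cells, Eya1, Gdnf and Meox1 were predicted at -1.36 or lower. This bound is 0.5 of the Cited1 change. Their median was 0.0823 (Eya1 0.21, Gdnf 0.08, Meox1 -0.37), which argues against a loss shared by all cells that express these genes. Fewer of the earliest progenitors alone, which Cited1 marks, cannot be excluded by this test. With sex as a term, Cited1, which is X-linked, differed by -2.77 between KO and the male WT array, which argues against the imbalance of the sexes as the cause of its fall. An unequal effect of Dot1l loss on genes of the same cells is a candidate explanation that remains a hypothesis, since slide row was not separable from group.

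Six3 was higher in KO. The highest upper 95% bound among Six2, Six4 and Six5 was 0.272, while the red signal at the Six3 probe was 273 to 684 units on KO2 to KO4 against 59.5 to 62 units on WT2 to WT4, which argues against cross-hybridisation of their transcripts; other Six genes were not tested, and the size of the Six3 change is uncertain because the probe was not well above background on WT2 to WT4. The green signal of the common reference at the Six3 probe was itself higher on KO2 to KO4 than on WT2 to WT4, by a measured 1.5 against a 99th percentile of 0.208 over all genes; the size is not exact, since WT2 to WT4 lay at the level of the negative controls, but KO2 to KO4 lay above it at 51 to 83 units, consistent with a signal at this probe that is not from the sample RNA alone. Leaving out Six2, which such a construct can carry, the 10 nearest tested genes had a median change of 0.0984, which an extra Six3 copy on the Cre construct would allow, but without a group carrying Cre alone such a copy and Dot1l loss cannot be told apart.

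Single arrays stood apart from the rest of their group in 10 of 134 sets of 4 values tested, where chance gives 6.7. The red negative-control medians of WT1 (1361 units) and KO1 (478.2 units) lay far above those of their groups, and the green correlations of WT1 (0.505) and KO1 (0.822) far below. The WT2 array stood apart for Ddx3y (3.30) and Xist (-2.68). The log2 ratio of Ugt2b38 was 0.977 in KO2 against 1.42 to 1.46 in the other KO arrays. In WT4 the ratios of Slc22a18 (-0.148), Ndrg1 (-0.987) and P4ha2 (-0.754) lay below those of the other WT arrays. Among 5612 array identifiers without a gene symbol, which the comparison of genes did not use, 13 passed (10 higher, 3 lower in KO), with 397 at an unadjusted p under 0.05 in limma.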

How the results depend on the processing

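The settings without WT1 and KO1 and with sex as a term were chosen only after the results were seen; where a result moved, the cause was not tested. Against 295 changed genes (219 higher, 76 lower), the software's own ratios and the deposited value table each gave 124 (74 higher, 50 lower), median centring 0 and the red channel alone 0 in either direction (177 and 107 genes at an unadjusted p under 0.05 in limma), array weights 453 (340 higher) and sex as a term 12 (4 higher, 8 lower). The replicate block gave 554 (443 higher) and all 295 genes passed in it; it changed no call of a list as a set, and no called gene lost its call. Leaving out 1 array gave 83 to 344 changed genes (51 to 263 higher, 32 to 81 lower), with 83 without KO4, 122 without WT4, 143 without KO2, 148 without WT2 and 188 without WT1; the higher genes were also fewer without KO3 (137). Without WT1 and KO1 together, the red channel alone gave 109 (69 higher, 40 lower), median centring 9 (7 higher, 2 lower), the replicate block 532 (408 higher, 124 lower) and the software's ratios 63 (36 higher, 27 lower). In the red channel alone the median over all genes moved to 0.334, and 276 of the 295 genes kept their direction; all 295 kept it with the software's ratios, median centring and the replicate block.

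Of the 10 lists that passed at the preset correlation, 5 passed with the red channel alone and 0 with an estimated correlation. With the red channel alone but without WT1 and KO1, only the loop of Henle list of these 10 did not pass (camera adjusted p = 0.123). The Dot1l difference, never past the threshold, turned to -0.0151 with the software's ratios, -0.0151 with the deposited table, and, without WT1 and KO1, to -0.0938 in the red channel alone, -0.0195 with median centring and -0.00783 with the software's ratios; leaving out 1 array it ranged from 0.00 to 0.06. With the red channel alone Phf19 turned to 0.30, Bmp2 to 0.11, Robo2 to 0.41, Akr1b7 to 0.13 and Egr1 to 0.22. Without WT1 and KO1, none of 61 named genes, Dot1l apart, changed direction in the red channel alone, and 22 of 46 kept their call. Of 47 named genes that passed, 24 passed with the software's ratios and 0 with median centring. With sex as a term, which leaves 1 WT array to compare with, all 295 genes kept their direction. In 291 of them this was fixed in advance, since the groups of the main comparison, that array included, did not overlap. The median size of the change of the 295 genes was 0.599 against 0.57, and the median SE was 0.163 against 0.105. Signal over background limits Six3, which was well above background on 1 of 4 WT arrays.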

Other observations

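The genes in this part were chosen only after their values in the main comparison were seen. They are single genes, and no group they belong to was tested. Among the genes that rose in KO were H2-K1 (0.88 ± 0.14, SE, adjusted p = 0.00837) and H2-Q7 (0.48 ± 0.11), which encode class I heavy chains, and B2m, which encodes their shared light chain (0.59 ± 0.14). Others were Ugt2b5 (1.26 ± 0.14), the sulfotransferase gene Sult1c2 (1.01 ± 0.19), the bile acid receptor gene Nr1h4 (0.98 ± 0.15), Cbr2 (1.01 ± 0.11), Gstm1 (0.56 ± 0.12) and Apoe (0.60 ± 0.10). Afp, the fetal serum protein gene, rose by 0.89 ± 0.11. H2-K1 and H2-Q7, like Ugt2b5, belong to families of similar sequence, so the member concerned is uncertain.

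Among the genes that fell in KO, the homeobox gene Emx1 fell by 0.92 ± 0.12, the zinc finger gene Osr2 by 0.86 ± 0.12, the Wnt modulator gene Dkk2 by 0.80 ± 0.11, the phosphatase gene Dusp9 by 0.58 ± 0.09 and Eya2 by 0.54 ± 0.10. Elavl4, a neuronal RNA-binding protein gene, fell by 0.97 ± 0.11 and Tph1, of serotonin synthesis, by 0.91 ± 0.14. The X-linked gene Eif2s3x fell by 0.60 ± 0.10, in a comparison in which the KO embryos were male and most WT embryos female.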
